A study of Mus musculus with 6 samples.

How the data were processed

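RNA sequencing was carried out on 6 libraries from mouse 3T3-L1 cells, an embryonic fibroblast line of pre-adipocytes that can be induced to store fat. Per the labels, cells were depleted of METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) into mRNA, or of FTO, an enzyme that removes methyl groups from RNA. Per the labels' protocols, RNA came from transiently transfected cells, was selected with poly(dT) oligonucleotides and then cleared of ribosomal RNA. Libraries were made from about 2.5 µg of RNA with a TruSeq v2 kit and read on a HiSeq2000 with reads of 101 bp. The file headers name the knockdown columns with an "si" prefix before the targeted gene, and the labels do not state what the control cells received. The METTL3 control and METTL3 knockdown groups had 2 libraries each, read in single-read mode. The FTO control and FTO knockdown groups had 1 library each, read in paired-end mode, so sequencing mode follows the experiment and each comparison was made within 1 mode. The labels do not say that replicates came from separate cultures, so p-values of single genes measure only the spread between these samples, which may be technical. Those of gene lists share this limit and also rest on the spread between genes.

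Each deposited table gave, per the file headers, a read count and an RPKM value for every Ensembl gene of 1 library. The read counts were whole numbers that the authors had not normalised. The RPKM values (read counts scaled by gene length and by a read total) were made by the authors, and the gene lengths and read totals behind them are not given in the sources used here. For each gene the ratio of count to RPKM was the same in all libraries up to 1 factor per library. Relative to the summed counts, the read total implied by RPKM was 1.20 times as large in the FTO control and 1.19 times as large in the FTO knockdown library as in the first METTL3 control library. TopHat2 2.0.9, bedtools and the genome build mm10 are named in the submitters' processing notes, with no role stated. Whether reads were counted by strand, how reads with several matches were counted, and whether the ends of a read pair were counted separately are not given in the sources used here. Gene symbols and positions came from GENCODE mouse release 21 on GRCm38, the assembly also called mm10. Of 37315 gene entries, 35449 matched a symbol, and 3 that repeated a symbol were left out in favour of the entry with most reads. At least 1 read was present for 23444 entries.

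Total counts per library ran from 28348179 to 44580722. A count of 0 in a library allows a true level of up to 3 reads, or 0.0673 to 0.106 CPM (counts scaled by library size). Exact Poisson intervals at 95% were computed for the single FTO libraries. Such intervals cover counting error only, and would be too narrow if the 2 ends of a pair were counted separately.

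The METTL3 groups were compared on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, robust quasi-likelihood fits (glmQLFit, glmQLFTest) without a replicate block, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and every adjusted p of a gene below comes from this two-sided test unless another tool is named. Levels are TMM-scaled CPM, given as mean ± SD over the 2 libraries of a group. SE is an approximate standard error of the log2 fold change, derived from the test. It is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided, adjusted over the lists). The preset correlation treats genes as nearly independent. Camera with a correlation estimated for each list, and fry, served as alternatives. An estimated correlation rests on the few residual degrees of freedom of 2 libraries per group. No METTL3 list was called with it (camera adjusted p = 0.928 to 0.968), so it cannot decide whether a list changed. Lists with fewer than 3 tested genes were not given to camera.

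For FTO, with 1 library per group, no test between conditions is possible without borrowing a spread from other groups. The change was log2((CPM + 1)/(CPM + 1)), knockdown over control, for genes with at least 50 reads in either library. The pseudocount of 1 CPM understates the change of weakly expressed genes, and folds printed for FTO are ratios of CPM without it. The number of genes past 2-fold was set beside the number between replicate libraries of the METTL3 groups. The median change of each list was ranked among 10000 random lists of the same size matched on mean expression, and a list was taken to stand apart outside the central 95% of these. This rank describes the 2 libraries and is no test of the conditions. Some medians are also given after removing the part linear in the difference between METTL3 libraries numbered 2 and 1, or a smooth trend on GC content and gene length. The first of these was chosen after the results were seen. It would also take away a true change that runs along that difference. METTL3 and FTO changes were correlated across genes.

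There were 21 gene lists, fixed before the data were examined. The 14 biology lists were m6A machinery, SR splicing factors, pro-adipogenic regulators, anti-adipogenic regulators, adipocyte markers, fibroblast matrix, interferon response, p53 targets, S-phase genes, mitotic genes, unfolded protein and integrated stress response, sterol biosynthesis, immediate early genes, and NF-kB and cytokine genes. The 6 lists of other cell types were myofibroblast and smooth muscle, skeletal muscle, osteoblast and cartilage, macrophage, epithelial and endothelial markers. The remaining list held replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, as a sign of RNA selection. Lists were drawn up from general knowledge, not from these samples.

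Named genes followed a rule also fixed before the data were examined. For METTL3 it took Mettl3 and Fto, up to 6 called genes in each direction with a mean of at least 5 CPM and no overlap between groups, the 2 members of each biology list with the smallest p, and 1 member of each other list. For FTO it took Fto and Mettl3, the 6 highest and 6 lowest genes with at least 50 reads in a library, and the 2 members (1 for the other lists) with the largest absolute change. Members of a list that passed when adjusted over the list alone are also named. Genes named outside this rule are said to have been chosen after their values were seen.

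The edgeR and camera steps were tested on simulated counts with known changes. Alternatives covered scaling, low-count filters, DESeq2 1.42.0, limma-voom, limma on the deposited RPKM, the replicate number as a block, other control groupings, leaving out each library, and entries sharing a symbol. Copies of Gapdh were found with blastn 2.17.0 as pseudogenes at least 95% identical to its mRNA. Plots were drawn with matplotlib 3.10.9. No m6A measurement, protein measurement or differentiation assay was analysed here. The result for 1 gene is not reported here.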

Results

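Gene expression was profiled by RNA sequencing in 3T3-L1 pre-adipocytes depleted of METTL3 or of FTO and in control cells. The METTL3 experiment comprised 2 control libraries with 43254253 and 41773967 counted reads and 2 knockdown libraries with 41841866 and 44580722. The FTO experiment comprised 1 control library with 29321128 reads and 1 knockdown library with 28348179. Mitochondrially encoded genes took 0.605% and 0.757% of the reads in the METTL3 controls and 0.679% and 0.687% in the METTL3 knockdowns, against 4.14% in the FTO control and 3.90% in the FTO knockdown. The first principal component held 90.7% of the variance across the 6 libraries and separated the FTO libraries (64.7 and 80.8) from the METTL3 libraries (-41.1 to -31.0), which also differ in sequencing mode. Replicates within a METTL3 group differed with a chi-square per gene of 49.3 for the controls and 50.1 for the knockdowns, so neither pair was 1 library deposited in duplicate, which does not show separate cultures.

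The targeted genes were measured first. Mettl3 (ENSMUSG00000022160, protein coding, GRCm38 chromosome 14, 52294841 to 52305128) stood at 25.1 and 28.9 CPM in the METTL3 controls and at 7.68 and 6.55 CPM in the METTL3 knockdowns. Its level in the knockdowns was 0.264 times the control level (log2 fold change -1.92, SE 0.16, n = 2 per group). By edgeR this missed the threshold over all 13697 genes tested (adjusted p = 0.161) and passed it when adjusted over the list alone (adjusted p = 0.000706 among the m6A machinery). Over all genes Mettl3 passed by edgeR without a low-count filter (adjusted p = 0.000750) and by DESeq2 (adjusted p = 3.0e-18). It also passed by edgeR with the replicate number as a block (adjusted p = 1.6e-29), whose meaning the labels do not give. It did not pass with other scalings, a stricter filter or limma. Fto (ENSMUSG00000055932, protein coding, chromosome 8, 91313525 to 91668439) was at 144 ± 3.02 CPM in the METTL3 controls and 140 ± 8.10 CPM in the METTL3 knockdowns (SD, n = 2), with a log2 fold change of -0.04 (SE 0.10, adjusted p = 0.908). In the FTO experiment Fto was counted 4484 times in the control (155 CPM, 95% interval 150.3 to 159) and 1413 times in the knockdown (49.2 CPM, 46.7 to 51.9), a log2 ratio of -1.63. Mettl3 was at 15.2 CPM in the FTO control and 17.8 CPM in the FTO knockdown (log2 ratio 0.22).

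**Figure D1:**
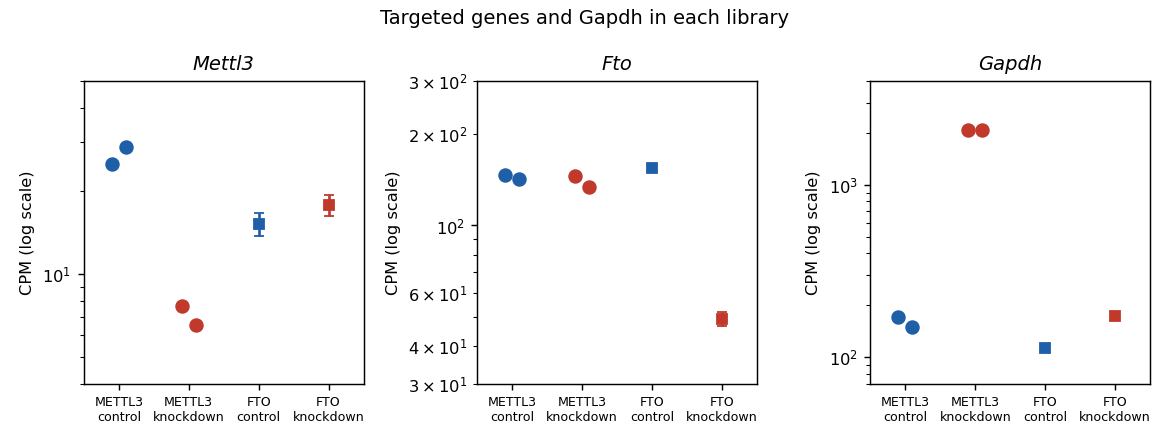
Level of Mettl3, Fto and Gapdh in each library, in TMM-scaled CPM on a log axis, with circles for the METTL3 libraries and squares for the FTO libraries, blue for control and red for knockdown. Bars on the squares are exact 95% Poisson intervals, smaller than some symbols. Mettl3 was at 7.68 and 6.55 CPM in the METTL3 knockdowns, Fto at 49.2 CPM in the FTO knockdown, and Gapdh at 2072 and 2073 CPM in the METTL3 knockdowns against 171 and 149 CPM in their controls.

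The METTL3 comparison asks which transcripts differ between cells with and without METTL3. Gapdh, which encodes a glycolytic enzyme often used as a reference gene, was 12.9-fold higher in the METTL3 knockdowns (2072 ± 0.793 CPM) than in the METTL3 controls (160 ± 15.7 CPM; SD, n = 2 each). Its log2 fold change was 3.69 (SE 0.12, adjusted p = 0.00420). Ranked by read count, Gapdh stood at 1190 and 1439 in the METTL3 controls and at 28 and 25 in the METTL3 knockdowns. The direction of the comparison does not tell which of the 2 groups was the unusual one. Gm13394 (ENSMUSG00000083773, chromosome 2, 28933610 to 28934609) rose with it, from 18.2 ± 3.65 to 285 ± 10.2 CPM (log2 fold change 3.97, SE 0.17, adjusted p = 0.00917). Gm13394 is annotated as a processed pseudogene and is 99.9% identical to Gapdh (ENSMUSG00000057666, chromosome 6, 125161715 to 125166467) over 1000 bp, so the assignment of reads between them is uncertain. Gapdh and its copies together summed to 180 ± 19.4 CPM in the METTL3 controls and 2369 ± 9.37 CPM in the METTL3 knockdowns, and to 857 CPM in the FTO control and 893 CPM in the FTO knockdown.

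These were the only 2 genes called by edgeR, both higher, with 0 genes called lower. At an unadjusted p under 0.05 lay 1569 genes, 870 higher and 699 lower, where 685 would be reached by chance. With 2 libraries against 2, an exact permutation test of 1 gene cannot give a p below 0.333. Levels did not overlap between the groups for 43.0% of genes, against 33.3% by chance. The count depended on the method: DESeq2 called 237 genes (169 higher, 68 lower) and edgeR without a low-count filter 111. With the replicate number as a block edgeR called 3706 (2016 higher, 1690 lower). The labels do not say that a number marks a shared batch. With the 3 controls of both experiments as 1 group, which mixes sequencing modes, edgeR called 0. In that last fit Gapdh had an adjusted p = 0.0850 and Gm13394 a log2 fold change of 1.22 (adjusted p = 0.929). Mettl3 itself had a log2 fold change of -2.04 without METTL3 knockdown replicate 1 and -1.82 without METTL3 knockdown replicate 2.

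In the unfolded protein and integrated stress response list, 8 of 22 members rose and 2 fell by edgeR when adjusted over the list alone, 12 did not pass, and 0 passed by edgeR over all genes. Trib3, a pseudokinase induced by ATF4, rose from 86.5 ± 13.4 to 182 ± 0.297 CPM (log2 fold change 1.07, SE 0.13, adjusted p = 0.00366, adjusted over the list alone, adjusted p = 0.187 over all genes). Chac1, which degrades glutathione, rose from 47.7 ± 2.13 to 86.1 ± 6.71 CPM (0.85, SE 0.11, adjusted p = 0.00366, adjusted over the list alone). Atf4, the transcription factor of this response (0.54), Asns, asparagine synthetase (0.58), Atf5 (0.57), Herpud1 (0.58), Slc3a2 (0.47) and Vldlr (0.58) also rose on this basis. The members that fell were Sdf2l1 (-0.61) and Creld2 (-0.47), which encode proteins of the endoplasmic reticulum. The chaperone Hspa5 stood at -0.20 and did not pass. Trib3 and Chac1 passed over all genes by edgeR without a low-count filter (adjusted p = 0.00483 and 0.0112) and by DESeq2 (adjusted p = 2.6e-07 and 8.9e-06). They did not pass with other scalings, a stricter low-count filter or limma. By edgeR with the replicate number as a block, whose meaning the labels do not give, both passed (adjusted p = 1.5e-23 for Trib3 and 2.5e-19 for Chac1). Without METTL3 knockdown replicate 1 their log2 fold changes were 1.07 and 0.93. As a list the median was 0.37, with a camera adjusted p = 0.119 (adjusted p = 0.928 with an estimated correlation).

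Regulators of fat cell formation moved in both directions. Among the 20 pro-adipogenic regulators, 2 rose and 1 fell by edgeR when adjusted over the list alone, 17 did not pass, and 0 passed by edgeR over all genes. The zinc finger factors Zfp467 (34.1 ± 0.485 to 51.5 ± 6.47 CPM, log2 fold change 0.59, SE 0.12) and Klf4 (95.4 ± 2.45 to 137.5 ± 13.1 CPM, 0.53, SE 0.11) rose (adjusted p = 0.0378, adjusted over the list alone for both), and both passed over all genes by DESeq2 (adjusted p = 0.0285 each). Pparg, the master regulator of adipogenesis, fell from 31.9 ± 0.615 to 23.4 ± 1.36 CPM (-0.45, SE 0.11, adjusted p = 0.0499, adjusted over the list alone). Of 15 anti-adipogenic regulators, 2 rose by edgeR when adjusted over the list alone and 13 did not pass. These were Wnt6, a secreted WNT ligand (8.99 ± 1.57 to 17.7 ± 2.13 CPM, 0.98, SE 0.18), and Ddit3, which encodes CHOP, a dominant inhibitor of C/EBP factors (105 ± 20.6 to 166.5 ± 8.97 CPM, 0.67, SE 0.16). DESeq2 called Wnt6 (adjusted p = 0.00257) and Ddit3 (adjusted p = 0.0289) over all genes, as did edgeR without a low-count filter for Wnt6 (adjusted p = 0.0422). None of the 13 adipocyte markers measured passed by edgeR. Fabp4 was at -0.40 (SE 0.12, adjusted p = 0.240, adjusted over the list alone) and Agpat2 at 0.19 (SE 0.10). Camera gave adjusted p = 0.626, 0.320 and 0.848 for the pro-adipogenic, anti-adipogenic and adipocyte lists.

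In the m6A machinery list Mettl3 alone passed of 20 members by edgeR when adjusted over the list alone. Igf2bp3, a reader protein, stood at -0.26 (SE 0.09, adjusted p = 0.342, adjusted over the list alone), and the median was 0.01 (camera adjusted p = 0.788). Of the 12 SR splicing factors 0 passed by edgeR, with Srsf5 at -0.17 and Tra2a at -0.23 (camera adjusted p = 0.903). In the list of 25 fibroblast matrix genes, 1 rose and 1 fell by edgeR when adjusted over the list alone. Timp2, an inhibitor of matrix metalloproteinases, rose from 446 ± 84.5 to 893 ± 60.9 CPM (1.00, SE 0.16), and Lox, the collagen cross-linking enzyme, fell from 1818 ± 181 to 862 ± 203 CPM (-1.08, SE 0.19; adjusted p = 0.0215, adjusted over the list alone for both). Timp2 and Lox passed over all genes by edgeR without a low-count filter (adjusted p = 0.0148 and 0.0422) and by DESeq2 (adjusted p = 3.1e-05 and 7.6e-05). They passed neither with other scalings nor with a stricter filter or limma. Timp2 also passed by edgeR with the replicate number as a block (adjusted p = 2.9e-25). Lox stood at -1.34 without METTL3 knockdown replicate 1. The list median was -0.05 (camera adjusted p = 0.498). Among 19 NF-kB and cytokine genes, the interleukin 33 receptor gene Il1rl1 rose (0.68, SE 0.14) and the chemokine gene Cxcl12 fell from 1588 ± 84.5 to 980.5 ± 145 CPM (-0.70, SE 0.13), both with adjusted p = 0.0378, adjusted over the list alone by edgeR (camera adjusted p = 0.498 for the list, and adjusted p = 0.968 with an estimated correlation). The list passed without METTL3 knockdown replicate 2 (camera adjusted p = 0.0244), leaned the other way without METTL3 knockdown replicate 1 (0.954), and had 0.332 and 0.831 without METTL3 control replicates 1 and 2. DESeq2 called Il1rl1 (adjusted p = 0.0246) and Cxcl12 (adjusted p = 0.00516) over all genes, as did edgeR without a low-count filter for Cxcl12 (adjusted p = 0.0430).

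Camera called 2 lists, both lower in the METTL3 knockdowns. Fry called neither (fry adjusted p = 0.660 for immediate early genes and 0.745 for replication-dependent histones). Of 21 immediate early genes, which respond to growth factors within minutes, 17 had a negative and 4 a positive log2 fold change, with a median of -0.20 (camera adjusted p = 0.0113, and adjusted p = 0.928 with an estimated correlation). No single member passed by edgeR. Fosb stood at 69.7 ± 27.2 CPM in the controls and 22.3 ± 10.1 CPM in the knockdowns (-1.64, SE 0.40), and Nr4a1 at 67.3 ± 2.21 and 48.4 ± 3.92 CPM (-0.48, SE 0.11), each with adjusted p = 0.0636, adjusted over the list alone by edgeR. DESeq2 called Fosb lower over all genes (adjusted p = 0.00100). Of 20 replication-dependent histone genes 16 were negative, with a median of -0.31 (camera adjusted p = 0.0113, and adjusted p = 0.928 with an estimated correlation). Hist1h1d was at 1.24 ± 0.0564 CPM in the controls and 0.574 ± 0.264 CPM in the knockdowns (-1.10, SE 0.38, adjusted p = 0.372, adjusted over the list alone). The histone call was lost without METTL3 control replicate 2 (adjusted p = 0.195) or without METTL3 knockdown replicate 1 (adjusted p = 0.506).

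Cell cycle and sterol genes leaned higher without passing in the fit without a block. All 26 S-phase genes had a positive log2 fold change (median 0.24, camera adjusted p = 0.0629), among them the helicase subunit genes Mcm3 (0.44, SE 0.27) and Mcm2 (0.28, SE 0.17). All 24 mitotic genes were positive as well (median 0.26, camera adjusted p = 0.0905), with the kinetochore gene Cenpf at 0.63 (SE 0.32) and the topoisomerase gene Top2a at 0.38 (SE 0.23). The 2 control libraries differed from each other by more than this, with medians of 0.61 for S-phase and 0.76 for mitotic genes, replicate 2 over replicate 1. Both lists leaned higher without METTL3 control replicate 2 or METTL3 knockdown replicate 1, and lower without METTL3 control replicate 1 or METTL3 knockdown replicate 2. Leaving out 1 library unbalances the library numbers between the groups. Over both groups, number 2 exceeded number 1 by medians of 0.62 for S-phase and 0.76 for mitotic genes. That difference has the direction of each of these flips. With all 4 libraries both had adjusted p = 0.968 with an estimated correlation. With the replicate number as a block, whose meaning the labels do not give, camera gave adjusted p = 6.7e-06 for S-phase and 5.1e-06 for mitotic genes. Among 24 sterol biosynthesis genes 19 were positive (median 0.20, camera adjusted p = 0.0515), including Pmvk (0.29, SE 0.10) and Fdft1 (0.30, SE 0.11), which code for enzymes of the mevalonate and squalene steps. The sterol list passed with library totals in place of TMM (adjusted p = 0.0476), without METTL3 control replicate 1 (0.00349) and without METTL3 knockdown replicate 2 (0.0162), but not without METTL3 control replicate 2 (0.831) or METTL3 knockdown replicate 1 (0.449). For this list, number 2 minus number 1 had a median of -0.16 over both groups. Between the METTL3 controls it was -0.26, more in size than the list median of 0.20. When a missing library unbalances the numbers, that difference has the direction of these shifts. With all 4 libraries the sterol list had camera adjusted p = 0.968 with an estimated correlation.

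Interferon and p53 genes showed no common direction. Of 28 interferon response genes 13 were positive and 15 negative (median -0.02, camera adjusted p = 0.848) and 0 passed by edgeR. Oasl1 was at 0.246 ± 0.0119 and 0.557 ± 0.0343 CPM and the chemokine gene Cxcl10 at 10.8 ± 3.58 and 6.30 ± 0.109 CPM in controls and knockdowns, each with adjusted p = 0.356, adjusted over the list alone by edgeR. This list leaned higher without METTL3 control replicate 1 or METTL3 knockdown replicate 2, and lower without METTL3 control replicate 2 or METTL3 knockdown replicate 1. Its median difference between METTL3 libraries numbered 2 and 1 was -0.60. With the numbers unbalanced by a missing library, that difference has the direction of each of these flips. With all 4 libraries the list had camera adjusted p = 0.968 with an estimated correlation. Of 20 p53 targets 0 passed by edgeR (median 0.02, camera adjusted p = 0.848). The growth-restraining gene Btg2 stood at -0.52 (SE 0.10, adjusted p = 0.0609, adjusted over the list alone) and Sesn1 at -0.40 (SE 0.10, adjusted p = 0.101, adjusted over the list alone). DESeq2 called Btg2 lower over all genes (adjusted p = 0.0463).

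Tek, an endothelial receptor gene, was the only marker to pass when adjusted over the list alone (0.246 ± 0.0212 to 0.681 ± 0.175 CPM, adjusted p = 0.0203 by edgeR), in a list with 2 tested genes. All 4 macrophage markers tested were positive (median 0.37, camera adjusted p = 0.0564, and adjusted p = 0.928 with an estimated correlation), with Csf1r at 3.39 ± 0.842 and 5.29 ± 0.935 CPM. The macrophage list passed with library totals (camera adjusted p = 0.0476) and without a low-count filter (camera adjusted p = 0.0148). It leaned higher with any 1 METTL3 library left out. Myofibroblast and smooth muscle markers had a median of -0.20 over 8 genes (camera adjusted p = 0.848). Myl9 was at 56.3 ± 40.1 CPM in the controls and 20.2 ± 7.13 CPM in the knockdowns. For the 5 osteoblast and cartilage markers the median was -0.02 (camera adjusted p = 0.848), with Alpl at 0.472 ± 0.439 and 0.320 ± 0.212 CPM. Skeletal muscle (2 genes, Des at 0.32) and epithelial markers (1 gene, Krt5 at 0.36) were too few for camera and none passed by edgeR.

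The FTO comparison asks the same of cells with and without FTO, with no replicate check because each group held 1 library. The FTO knockdown library had less mRNA for many matrix proteins and more for the secreted protease MMP13 and the cytokine interleukin 1 alpha. The lowest genes were Ptn, the heparin-binding growth factor pleiotrophin (362 to 78.1 CPM, log2 ratio -2.20), and the matrix genes Postn (-2.19), Abi3bp (-2.16), Dpt (-2.04), Ogn (-1.85) and Aspn (-1.75). The highest were Mmp13, the gene of collagenase 3 (19.9 to 119 CPM, 2.52), Prl2c2, which codes for proliferin (55.5 to 243 CPM, 2.11), Il1a (1.56), the purinergic receptor gene P2rx3 (1.53), Gm15564 (2.55 to 9.03 CPM) and Tenm4 (1.40). Prl2c2 belongs to a family of similar genes, and Gm15564 is an antisense transcript overlapping other genes, so the read assignment of both is uncertain.

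In all, 129 of 11432 genes (1.13%) lay past 2-fold, 41 higher and 88 lower. Between replicate libraries of 1 group the number was 82 of 11711 for the METTL3 controls and 48 of 11765 for the METTL3 knockdowns. The SD of the log2 ratios was 0.32 for FTO against 0.28 for both replicate pairs. Borrowing the spread of the METTL3 groups, edgeR called 0 genes, with 1211 at an unadjusted p under 0.05 and a smallest adjusted p of 0.274. Fto itself was not called in that fit, at a log2 fold change of -1.65, so 0 calls there do not show that no gene changed. Lars2, a mitochondrial leucyl-tRNA synthetase gene named after its values were seen, was at 3783 CPM in the FTO control and 6218 CPM in the FTO knockdown, against 475 to 686 CPM in the 4 METTL3 libraries. Whether the reads counted there came from its mRNA was not tested.

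Of the lists with a median that could be ranked, 11 stood apart from random lists, 6 on the low side. Fibroblast matrix genes were lower in 22 of 23 cases, with a median of -0.54, below all 10000 random lists, and -0.31 after removing the part linear in the difference between METTL3 libraries numbered 2 and 1. Besides Postn, the members past 2-fold included Lox (1449 to 636 CPM, -1.19) and the collagen gene Col6a1 (727 to 356 CPM, -1.03), while Fn1 stood at -0.01. All 24 sterol biosynthesis genes were lower (median -0.44, below all random lists). Among them were Mvd (113 to 59.0 CPM, -0.93) and Mvk (83.4 to 43.5 CPM, -0.92), enzymes of the mevalonate pathway. Between the METTL3 control replicates the sterol median was -0.26, replicate 2 over replicate 1. The FTO sterol median was -0.34 after removing the number difference. Interferon response genes were lower in 14 of 17 cases (median -0.41, percentile 0.04), with Ifit3 at -1.01 and the signal transducer Stat2 at -0.99. Between the METTL3 control replicates the interferon median was -0.42, replicate 2 over replicate 1, and the FTO median was -0.15 after removing the number difference. Of 19 p53 targets 14 were lower (median -0.34, percentile 0.01), led by Trp53inp1 (-1.25) and Btg2 (-0.89). The p53 median was -0.15 after the same removal and -0.17 after removing a trend on GC content and gene length.

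Of 13 anti-adipogenic regulators 12 were lower in the FTO knockdown library (median -0.24, percentile 0.79). The pre-adipocyte factor Dlk1 went from 1704 to 1046 CPM (-0.70) and Klf2 from 14.6 to 7.67 CPM (-0.85). Adipocyte markers were lower in 11 of 12 cases (median -0.25, percentile 0.48), with the phosphatidate phosphatase gene Lpin1 at -1.09 and the lipid droplet gene Plin4 at -0.99. Pro-adipogenic regulators did not stand apart (7 higher, 11 lower, median -0.11, percentile 8.56), with Stat5a at -0.78 and Klf5 at 0.69. Their median was -0.0007 after removing the number difference and -0.01 after removing the trend on GC content and gene length.

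On the high side, 16 of 22 unfolded protein and integrated stress response genes were higher (median 0.29, above all random lists). Slc7a11, the cystine transporter, went from 25.9 to 56.0 CPM (1.09), Trib3 from 27.8 to 56.7 CPM (1.00), and Sdf2l1 was lower (-1.08). Set against the mean of the 3 controls of both experiments, the median of this list was -0.18 and Slc7a11 was at -0.12. That mean mixes sequencing modes. The FTO control differed past 2-fold from METTL3 controls 1 and 2 in 29.9% and 25.9% of genes, so this setting says little about the knockdown. All 26 S-phase genes (median 0.26) and 23 of 24 mitotic genes (median 0.26) were higher, both above all random lists, with Fen1 at 0.52, Gins1 at 0.49, Top2a at 0.51 and Bub1 at 0.50. The corresponding medians between the METTL3 control replicates were 0.61 and 0.76, and the FTO medians were 0.03 and -0.01 after removing the number difference. All 26 S-phase and all 24 mitotic genes were positive in the number difference itself. Its removal would therefore also take away a true change of these genes, and cannot decide between the 2. Of 12 SR splicing factors 11 were higher (median 0.23, percentile 99.77), led by Srsf3 (136.5 to 197 CPM, 0.52) and Srsf7 (0.50). In the m6A machinery 13 of 20 were higher (median 0.16, percentile 99.32), with the reader gene Ythdc2 at 0.51, although the list holds Fto itself.

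Immediate early genes split evenly (11 higher, 10 lower, median 0.02, percentile 65.17), with Ier3 at 1.00 and Fos at -0.87. NF-kB and cytokine genes were also mixed (10 higher, 9 lower, median 0.07, percentile 89.13). Ptgs2, the inducible cyclooxygenase gene, went from 172 to 412 CPM (1.25) and complement C3 from 438 to 182 CPM (-1.26). Replication-dependent histones had a median of -0.12 (percentile 22.58), with Hist1h2bc at -0.46. Among other cell types, 7 of 7 myofibroblast and smooth muscle markers were lower (median -0.16, percentile 9.44, Myl9 at -0.53) and the 3 macrophage markers had a median of 0.06 (percentile 65.86, Cd68 at -0.57). Skeletal muscle (Des at -0.40) and osteoblast and cartilage markers (Spp1 at -0.20) had 2 measured genes each, and epithelial and endothelial markers had 0. After removing the number difference the medians were -0.59 for myofibroblast and smooth muscle markers, -0.08 for macrophage markers, -0.09 for NF-kB and cytokine genes and -0.03 for replication-dependent histones. After removing the trend on GC content and gene length they were -0.13, 0.19, -0.04 and -0.02 in the same order. The immediate early median was -0.004 after the first removal and 0.11 after the second.

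**Figure D2:**
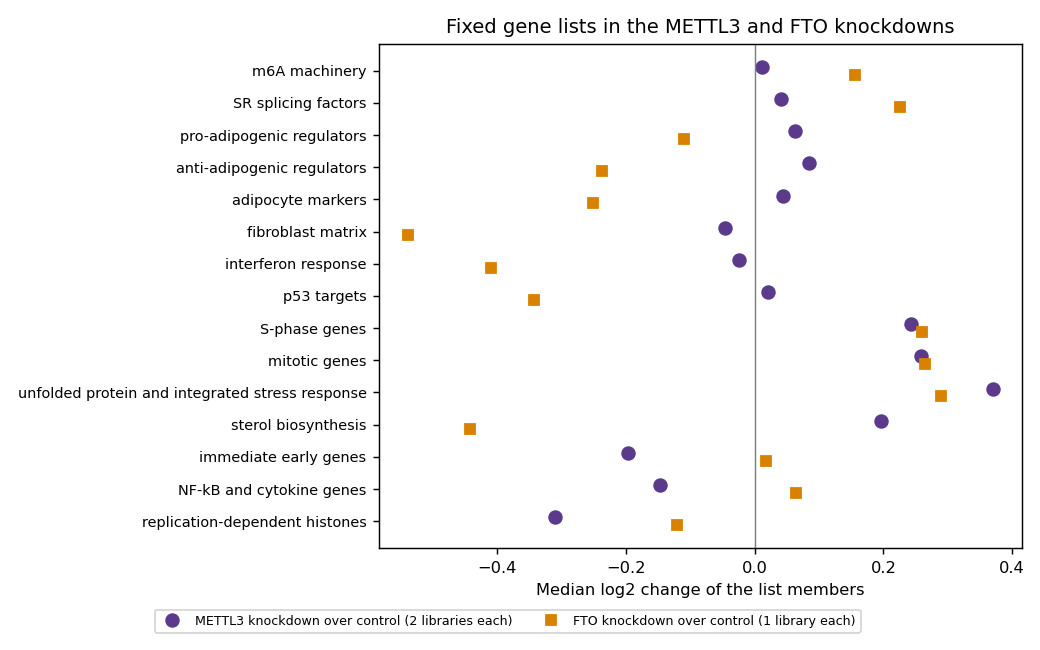
Median log2 change of the members of each biology list and of the histone list, knockdown over control, with purple circles for METTL3 and orange squares for FTO. Sterol biosynthesis genes lie at 0.20 for METTL3 and -0.44 for FTO, whereas S-phase genes lie at 0.24 and 0.26.

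**Figure D3:**
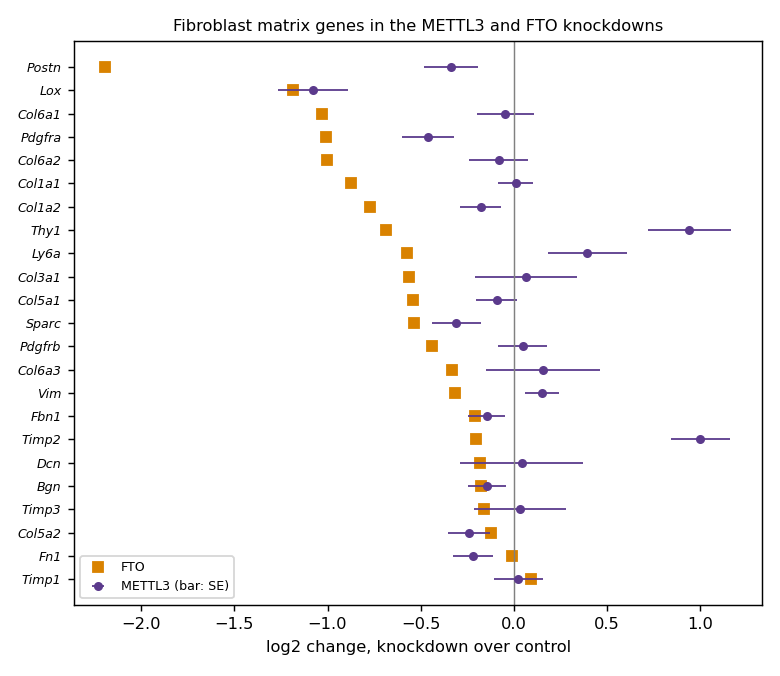
Log2 change of each measured fibroblast matrix gene, knockdown over control, for FTO (orange squares, 1 library per group, no error) and METTL3 (purple circles with SE, n = 2 per group). For FTO, 22 of 23 matrix genes lie below 0.

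The METTL3 and FTO experiments share no library, and deplete a writer and an eraser of RNA methylation, so their changes were set against each other. Across 11210 genes Pearson's r was 0.168 and Spearman's rho 0.182, and 56.8% of genes had the same sign. These are correlations across genes, which are not independent replicates, so no p was computed. In the unfolded protein and integrated stress response list 12 of 22 genes were higher in both knockdowns, among them Trib3 and Chac1, and 6 were lower in both, among them Sdf2l1. All 26 S-phase genes were higher in both, although the METTL3 list leaned lower without METTL3 control replicate 1 or METTL3 knockdown replicate 2. The FTO S-phase median was 0.03 after removing the number difference, which would also take away a true change of these genes. Of 24 sterol biosynthesis genes 19 were higher with METTL3 depletion and lower with FTO depletion. The sterol median also differed by -0.26 between the METTL3 control replicates, replicate 2 over replicate 1. The METTL3 change within libraries numbered 1 and that within libraries numbered 2 correlated at r = 0.733. The FTO change correlated with the difference between METTL3 libraries numbered 2 and 1 at r = 0.376.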

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

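The tests of the difference between the METTL3 and FTO changes, and those of the matrix pattern against differences between METTL3 replicates, were chosen only after the results were seen. The GC content and length test was set out before its result.

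In 8 lists the METTL3 and FTO changes differed by camera on the difference itself, in a fit of all 6 libraries that assumes the lone FTO libraries vary like the METTL3 groups. Values are the median over genes of METTL3 minus FTO on the log2 scale. None of the 8 differences was kept with an estimated correlation. No list at all passed in that setting (lowest camera adjusted p = 0.526), so it cannot decide. Sterol biosynthesis genes differed by 0.62 (adjusted p = 3.4e-09, and adjusted p = 0.526 with an estimated correlation), with medians of 0.20 for METTL3 and -0.44 for FTO. Anti-adipogenic regulators differed by 0.50 (adjusted p = 0.000231, and 0.526 with an estimated correlation), and p53 targets by 0.29 (adjusted p = 0.0230, and 0.526 with an estimated correlation). Fibroblast matrix genes differed by 0.48 (adjusted p = 0.000231, and 0.778 with an estimated correlation), and interferon response genes by 0.49 (adjusted p = 0.0230, and 0.897 with an estimated correlation). The 4 macrophage markers differed by 0.82 (adjusted p = 0.0346, and 0.526 with an estimated correlation). SR splicing factors were lower for METTL3 than for FTO by a median of -0.23 (adjusted p = 0.0346, and 0.847 with an estimated correlation), and replication-dependent histones by -0.22 (adjusted p = 0.0230, and 0.778 with an estimated correlation). For single genes the same fit called 0 differences, with 1044 at an unadjusted p under 0.05 and Gapdh at adjusted p = 0.0608. The targets Mettl3 (difference -2.17) and Fto (1.60) were not called either, so 0 calls there do not show that single genes changed alike. Both experiments also differ in sequencing mode, although each change was taken within 1 mode.

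The lower matrix genes in the FTO knockdown library, with a median of -0.54 over 23 genes, stay open to technical explanations. After removing a smooth trend on GC content and gene length the median was -0.39 (bootstrap SE 0.11), within its spread of the bound of -0.35 set beforehand for excluding such a bias. After removing the part linear in the difference between METTL3 libraries numbered 2 and 1, it was -0.31 (SE 0.13), so a difference in culture state of that kind may account for part of the pattern. The largest median between METTL3 replicate libraries was -0.22, but 2 replicate pairs are too few to bound ordinary variation between cultures. An effect of FTO depletion cannot be told apart from these with 1 library per group.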

How the results depend on the processing

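Alternatives were listed before the data were examined, whereas the tests below of the library numbers and of other splits were chosen after the results were seen. For the METTL3 comparison the 2 calls became 111 without a low-count filter, 237 with DESeq2 and 0 with all 3 controls as 1 group, and 2 to 70 when 1 library was left out (the lone library then assumed to vary like the others). The other scalings, filters, limma fits, the fit of all 6 libraries in 4 groups and treatments of shared symbols gave 2 or 3. Mettl3, Trib3, Chac1, Timp2 and Lox were not called in these. The 2 called lists became 4 with library totals, 0 with an estimated correlation, 0 with fry, and 3 to 5 when 1 library was left out. With 1 library left out the adjusted p of the interferon list ran from 0.000241 (lower, without METTL3 knockdown replicate 1) to 0.424, and it reversed to higher without METTL3 knockdown replicate 2 (adjusted p = 0.0107). For FTO, the 129 genes past 2-fold became 60 with RPKM and a pseudocount of 1, 220 with a pseudocount of 0.1 CPM, 2389 against the mean of the 3 controls, which mixes sequencing modes, and 0 calls in the fit that borrows the METTL3 spread; other settings gave 98 to 179. The 11 lists became 6 against the 3 controls, where the stress response list (-0.18) and Slc7a11 (-0.12) reversed. The correlation of METTL3 and FTO changes was 0.137 with METTL3 libraries numbered 1 only. Apart from the changes of direction that follow the library numbers, the cause of these shifts was not tested. Sign changes not counted as reversals were seen in 6 of 639 METTL3 gene values, 21 of 162 METTL3 list values, 3 of 405 FTO gene values and 4 of 34 FTO list values. These totals hold all alternative values, called or not. The correlation over called genes alone was not run, because 2 genes were called. On simulated counts for the METTL3 comparison edgeR recovered 81 of 100 genes changed 2-fold and 100 of 100 changed 4-fold. Beside these it made 19 false calls, over 13517 genes tested. Camera recovered a list shifted by 0.5 (adjusted p = 8.2e-14) with 0 other lists called. Genes were drawn independently and without a number effect in both of these simulations. They therefore cannot show how often correlated genes or library numbers would give false calls. Nor do they give the power in the real samples, where edgeR did not call Mettl3 at a log2 fold change of -1.92 (adjusted p = 0.161).

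With the replicate number as a block, edgeR called 3706 genes (2016 higher, 1690 lower) and camera 6 lists, adding S-phase, mitotic, sterol and macrophage genes, all higher. Without the block none of these was called with an estimated correlation (adjusted p = 0.928 to 0.968), which was not run with the block. The labels do not say that a number marks a shared batch or day, and 2 pairs are too few to establish it, so this fit is only a hint. The differences of library 2 from library 1 in the METTL3 controls and knockdowns correlated at 0.800 across genes, as a batch or culture difference shared by same-numbered libraries would give. Depth is argued against, since library 2 was 1.07 times as deep in the knockdowns but 0.966 times in the controls. GC content and length are argued against too, a test set out before its result: the mitotic median was 0.76 before and 0.764 after removing their trend. Which batch or culture difference it may be stays open. Of the 3 splits of the 4 METTL3 libraries, 1 (the real one) gave 2 or more calls and the highest other gave 0, too few splits to judge chance. The split by number had 2064 genes at an unadjusted p under 0.05 against 1569 for the real split and 15 for the other, which points to a structure of the samples. In simulated counts with such a number effect, edgeR without a block recovered 60 of 100 genes changed 2-fold (0 false calls over 13505 genes) and with the block 100 of 100 (9 false calls).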

Other observations

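The libraries carried expression features that belong to no comparison, named after their values were seen. Mdm2, the ubiquitin ligase gene that restrains p53, was among the abundant transcripts in all 6 libraries, at 4204 to 4776 CPM in the METTL3 libraries and 5418 and 5291 CPM in the FTO libraries. Wnt6 was at 7.91 to 19.1 CPM in the METTL3 libraries and at 0.624 and 0.420 CPM in the FTO libraries. Fosb was at 15.1 to 88.7 CPM in the METTL3 libraries and below 2 CPM in both FTO libraries (1.73 and 1.93). Il1rl1 went the other way, at 16.8 to 30.9 CPM against 267 and 289 CPM.

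Of 22 stress response genes 12 were higher in both knockdowns, 6 were lower in both, and 4 were lower for METTL3 and higher for FTO, among them Slc7a11 (-0.40 and 1.09). The difference between the METTL3 and FTO changes over this list had a median of -0.01 (camera adjusted p = 0.900), which does not show that the changes were equal. Among 16 other glycolysis genes, a list drawn up after the Gapdh value was seen, 15 were positive in the METTL3 knockdowns by edgeR, with Pkm at 0.30 (SE 0.10, adjusted p = 0.379) and Hk2 at 0.41 (SE 0.18, adjusted p = 0.460).

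The Gapdh difference in the METTL3 experiment was weighed against other explanations; the test on the FTO libraries was chosen only after the result was seen, and the tests on ribosomal and glycolysis genes were set out before theirs. A different counting of genes with near-identical copies is argued against by 78 ribosomal protein genes, which have many such copies and had a median log2 fold change of -0.0212 (range -0.24 to 0.22). A rise of the whole glycolysis pathway is argued against by the 16 other genes (median 0.206, highest 0.73, against 3.69 for Gapdh). A control reagent shared by both experiments is argued against by a log2 ratio of 0.0598 for Gapdh and its copies in the FTO knockdown over control. A reagent or culture difference that lowered Gapdh in the METTL3 controls alone may remain, as may an effect of METTL3 depletion, and the 4 METTL3 libraries cannot separate them.

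Reads were divided differently between Gapdh and its copies in the experiments. Gapdh itself took 87.2% to 89.8% of the summed level of Gapdh and its copies in the METTL3 libraries and 13.2% and 19.3% in the FTO control and knockdown. Gapdh alone was at 113 CPM in the FTO control and 172 CPM in the FTO knockdown (log2 ratio 0.60), while the sum was 857 CPM in the FTO control and 893 CPM in the FTO knockdown.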
